A study of Mus musculus with 16 samples.

How the data were processed

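RNA sequencing had been done on gonadal and subcutaneous fat of female mice that lack Lcn2 and received an adeno-associated virus carrying either LCN2 or GFP, with 4 samples per group and 16 in all. Sample groups and replicate numbers were taken from the labels. The labels do not say whether a number marks the same mouse in both depots. RNA was extracted from frozen tissue with an integrity number above 8.2, and libraries were made with a stranded mRNA kit, per the labels' protocols. HISAT2 and DESeq2 were used on the builds GRCm38 and mm10, per the submitters' processing notes. Their versions, the counting tool, its strand setting and the annotation are not given in the sources used here.

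For gonadal fat the authors deposited a table named as counts, but its values were a signal per gene already divided by 1 size factor per sample. Divided by what 1 read is worth in its sample, 100% of the values came out whole within a tolerance of 1e-06, and these are called recovered reads. Recovered totals were between 35173260 and 42890102 reads per sample, with a median of 37423116. In these libraries 3 reads equal between 0.0700 and 0.0853 CPM, a limit that covers counting error only. For subcutaneous fat the authors deposited rlog values, a log2 scale on which values of low genes are drawn towards the gene's mean, so fold changes are understated there. The depth of these samples is unknown. The tables hold 30325 gonadal and 30946 subcutaneous genes, of which 99.2% in each matched a symbol, and 29084 are in both. The tables had been normalized separately, so tests were run only within a table. Coordinates come from an annotation of GRCm38.

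The planned gonadal test, edgeR on counts, was replaced because the deposited values are not counts. It was kept on the recovered reads as an added alternative, in which it called 14 genes. The test used was limma 3.58.1 in R 4.3.3, with an intensity trend, on log2 of the normalized count plus 1, for the 19536 genes with a mean of at least 10. Fold changes on that scale understate the change of low genes. Subcutaneous rlog values were tested with limma as deposited, for the 20302 genes with a mean of at least 3. Differences are LCN2 minus GFP, errors are SE unless given as SD, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Lcn2 also had an exact permutation test in each depot. DESeq2 1.42.0 and edgeR 4.0.16 were run on recovered reads only.

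Before the data were examined, 35 lists had been fixed, 22 of gene functions and 13 of cell type markers. They were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, when at least 5 members were measured. This left 34 lists in gonadal fat, where the neutrophil list was too small, and 35 in subcutaneous fat. Named genes followed a fixed rule. It took Lcn2 and, per direction, up to 10 genes with the largest change among those past the threshold with groups that did not overlap. These needed a mean log2 CPM of at least 1 or a mean rlog of at least 5, and a symbol that is not a predicted or clone name. Where fewer than 10 passed, the smallest p-values filled the set. The rule also took up to 4 passing members of each list, or the 2 members with the smallest p where a called list had none. Some genes that the rule took are not reported here.

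Alternatives covered scaling, filters, tests, thresholds, a block for the replicate number and leaving out each sample in turn. Others were added after seeing the data, among them TMM scaling, other pseudocounts, marker scores as covariates and the removal of libraries with transcripts of other tissues. The run of the planned edgeR test on recovered reads was also added then. No pair of gonadal libraries agreed within sampling noise, the mean chi-square per gene over its 1 degree of freedom being at least 45.7. Among subcutaneous pairs the SD of the rlog difference was at least 0.198, and their sampling noise is unknown. Nothing in the labels besides the group size states that samples came from separate mice. P-values measure the spread between these samples.

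The tests were tried on simulated data with known changes. In 3 simulations of gonadal fat over 19208 genes, limma found 54.3% of the genes changed by 1 on the log2 scale and 86.9% of those changed by 2, with 6.59% false calls. DESeq2 found 70.3% and 88.7% over 19424 genes, with 24.9% false calls. For subcutaneous fat, over 20302 genes, limma found 85% and 95%, with 6.57% false calls. There the changes were added to the rlog values themselves. The drawing of low genes towards their mean was thus left out, so these shares may be too high for changes in reads. In both depots noise was independent between genes, so the shares of false calls may differ where genes vary together. A list shifted by 0.5 was called in 10 of 10 simulations in each depot. Genes were drawn independently there, so this does not show how list calls fare when members are correlated.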

Results

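The series profiled gene expression in fat of female mice of the C57BL/6J background that carry a null allele of Lcn2, the gene of the secreted siderophore-binding protein lipocalin-2. At 8 weeks of age the mice received an AAV8 vector with LCN2 or with green fluorescent protein (GFP), driven by the adiponectin promoter of fat cells. They were kept on an HF/HS diet and sampled at 16 weeks. Gonadal and subcutaneous fat were each profiled in 4 samples with the LCN2 vector and 4 with the GFP vector. Gonadal libraries held between 35173260 and 42890102 recovered reads, and the depth of the subcutaneous libraries is unknown. The comparison asked what LCN2 made by fat cells changes in the expression of each depot.

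Lcn2 was higher in all 4 LCN2 samples than in any GFP sample in both depots. In gonadal fat, Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252 on the minus strand, GRCm38) had a normalized count of 344 ± 182 (SD, n = 4) with the LCN2 vector and 81.2 ± 18.7 (SD, n = 4) with GFP. The log2 fold change was 1.93 ± 0.37 (SE). In subcutaneous fat the rlog value of Lcn2 was 9.12 ± 0.62 (SD, n = 4) against 8.17 ± 0.28 (SD, n = 4), a difference of 0.95 ± 0.29 (SE). The two-sided exact permutation p for Lcn2 was 0.0286 in each depot, the smallest that 4 against 4 samples allow. Lcn2 did not pass limma's test over all genes, with an adjusted p of 0.108 in gonadal and 0.308 in subcutaneous fat, and DESeq2 on recovered reads gave 1.28e-05 in gonadal fat. LCN2 replicates 3 and 4 had the highest Lcn2 values in both depots, with normalized counts of 522 and 481 against 186 and 189 in replicates 1 and 2 in gonadal fat. The labels do not say which part of Lcn2 the null allele lacks. Reads of Lcn2 in GFP samples, and the share of the vector in LCN2 samples, cannot be told from counts per gene.

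**Figure D1:**
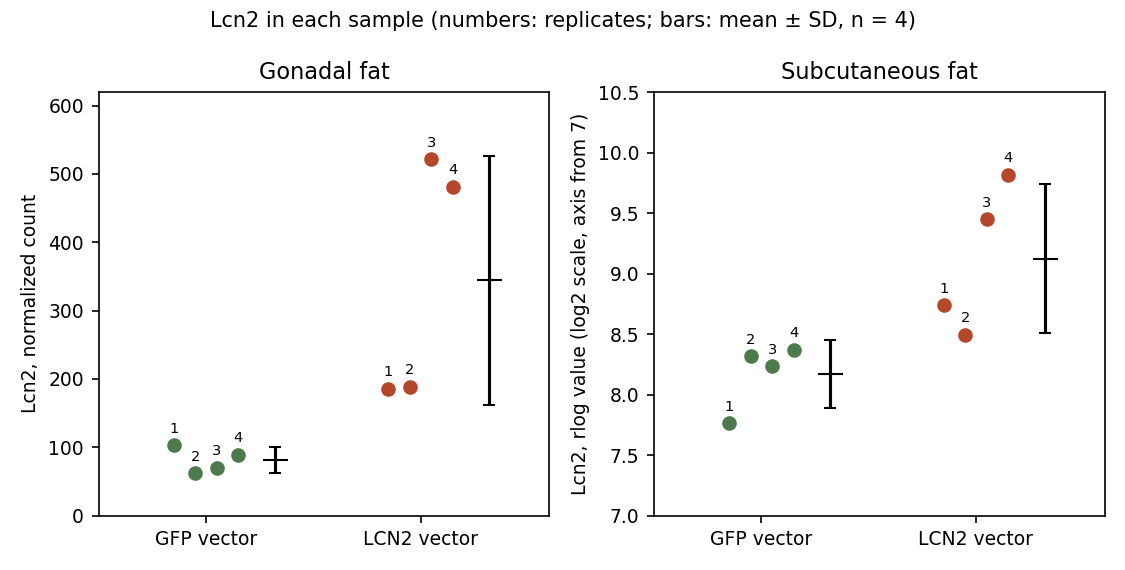
Lcn2 in each sample, as normalized counts in gonadal fat (left) and rlog values on a log2 scale in subcutaneous fat (right), with replicate numbers above the points and the mean ± SD of 4 samples beside them. All LCN2 samples lie above all GFP samples in both panels, and gonadal values with the LCN2 vector run from 186 to 522.

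In gonadal fat, 20 of 19536 genes changed with the LCN2 vector, 8 higher and 12 lower. Among those that rose was Tfr2, which encodes a second transferrin receptor, with a normalized count of 542 ± 176 (SD, n = 4) against 107 ± 23.1 (SD, n = 4) and a log2 fold change of 2.29 ± 0.26 (SE; limma, adjusted p = 0.0339). Noct, the rhythmically expressed nocturnin, rose from 882 ± 87.8 to 1921 ± 303 (SD, n = 4), a log2 fold change of 1.11 ± 0.12. Alpl, the tissue-nonspecific alkaline phosphatase, rose by 0.91 ± 0.11, Mtss1l, an actin-binding protein of the cell cortex, by 0.69 ± 0.09, and the olfactory receptor gene Olfr558 by 1.02 ± 0.14. Among those that fell, Tmem255a, which encodes a membrane protein, went from 300.3 ± 27.5 to 83.3 ± 8.73 (SD, n = 4), a log2 fold change of -1.84 ± 0.12 (limma, adjusted p = 0.00242).

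Cgn, Ppl, Wnt2b, Xpnpep2 and Stk26 also fell in gonadal fat with the LCN2 vector. Cgn, which encodes the tight junction protein cingulin, had a log2 fold change of -1.84 ± 0.22, Ppl, the gene of the desmosomal periplakin, one of -1.41 ± 0.19, and the Wnt ligand gene Wnt2b one of -1.83 ± 0.25. The aminopeptidase gene Xpnpep2 fell from 444 ± 35.6 to 135 ± 37.7 (SD, n = 4) and the kinase gene Stk26 from 340 ± 37.3 to 125 ± 32.0. For these 11 genes the adjusted p by limma lay between 0.00242 and 0.0493, and all 4 LCN2 samples lay on one side of all GFP samples. Car12, Gm38357 and D430019H16Rik also rose, and Gabrq, Sntg1, Vwc2, Gata5, Il31ra and 2010300C02Rik also fell. They did not meet the level or symbol part of the naming rule and were chosen here after their values were seen. Over all tested genes the groups did not overlap in 9.11%, where chance gives 2.86% on average. Genes are correlated, so a single split of the samples can lie far from that average.

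The remaining named genes did not pass. On the higher side with the LCN2 vector, Lzts1 had a log2 fold change of 1.18 ± 0.17, Palld, an actin-bundling protein gene, 1.12 ± 0.17, Itga7, a laminin-binding integrin, 0.80 ± 0.12, the progestin receptor gene Paqr7 0.70 ± 0.10 and Sipa1l1 0.50 ± 0.07. On the lower side were Cldn1, a tight junction claudin, at -2.13 ± 0.31, Bnc1, at -1.66 ± 0.24, Kcnab1, a potassium channel subunit, at -1.37 ± 0.21 and Gdf10, a ligand of the transforming growth factor family, at -0.82 ± 0.12. Their adjusted p by limma ran from 0.0586 to 0.0694. Tmem255a shares 10.6% of its exonic bases with Zbtb33 on the opposite strand. Olfr558 belongs to a large gene family whose reads the counting could have split.

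**Figure D2:**
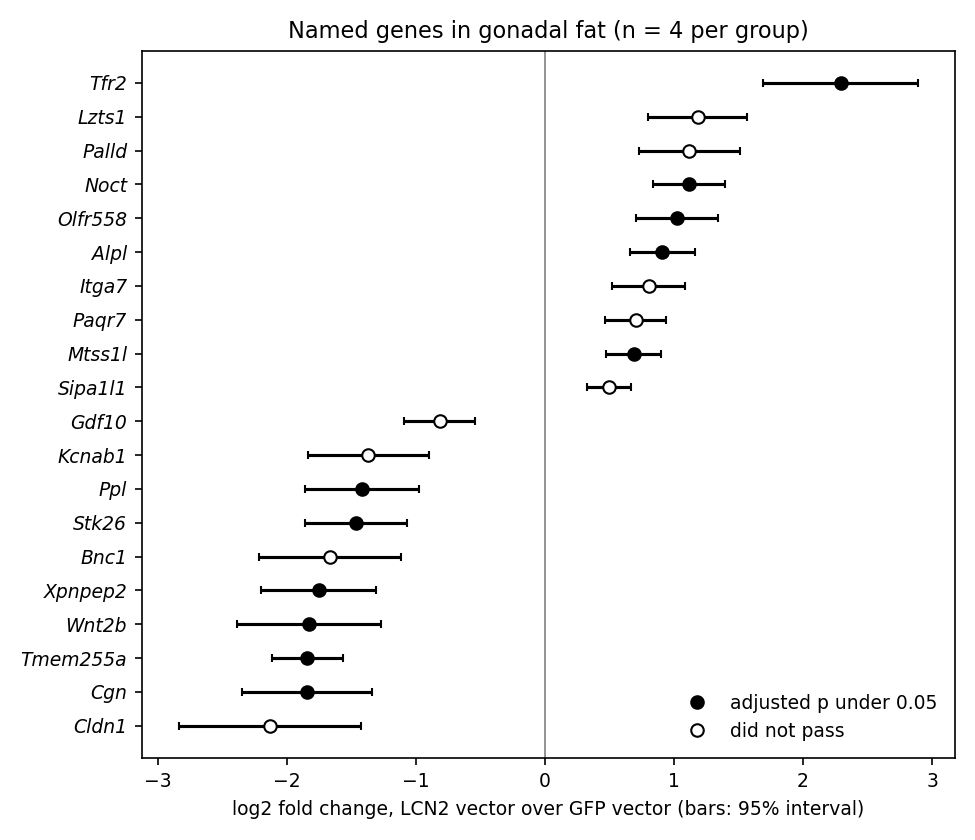
Log2 fold changes of the named genes in gonadal fat, LCN2 over GFP vector, with 95% intervals and 4 samples per group. Filled points passed an adjusted p of 0.05 by limma, from Tfr2 at 2.29 to Cgn and Tmem255a at -1.84, and open points did not.

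The count of gonadal genes moved with single libraries. It was 2, 1 and 1 without GFP replicates 1, 2 and 3, and 66 without GFP replicate 4. It was 1 without LCN2 replicate 3, 3 without LCN2 replicate 4, and 27 and 15 without LCN2 replicates 1 and 2. Tmem255a passed in each of these 8 fits. Scaling by library totals called 6 genes, 4 higher and 2 lower, and totals without the 10 most abundant genes called 10, 6 higher and 4 lower. DESeq2 on recovered reads called 776 genes, 437 higher and 339 lower, and these included all 20. Limma called no gene without LCN2 replicate 4 and GFP replicate 2, which had the highest medians of muscle markers, and 1689 genes then had an unadjusted p under 0.05. It called none without GFP replicate 1 and LCN2 replicates 1 and 2, which had the highest medians of hepatocyte genes, and 1622 then had an unadjusted p under 0.05. All 20 genes, which had been chosen for their change with all samples, kept their sign in both fits, with fewer samples. Their median absolute log2 fold change was 1.74 with all samples, 1.56 without the muscle libraries and 1.90 without the hepatocyte libraries, with a median SE of 0.20, 0.23 and 0.24.

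Markers of mesothelium, the cell layer that covers gonadal fat, were lower with the LCN2 vector. All 12 measured members had a negative log2 fold change, with a median of -1.23. Camera called the list (adjusted p = 5.80e-10, but adjusted p = 0.973 and unadjusted p = 0.0743 with an estimated correlation). No member passed over all genes, while 8 of 12 did with p adjusted over the list alone. Bnc1, with -1.66 ± 0.24, and Wt1, the transcription factor gene of mesothelium and podocytes, with a normalized count of 405 ± 120 (SD, n = 4) against 980 ± 299 (SD, n = 4), had the smallest p. The list's medians per sample overlapped, with LCN2 replicate 2 at 0.22 and GFP replicate 3 at 0.15. The list's share of recovered reads was 0.0317% to 0.0850% in GFP samples and 0.0203% to 0.0417% in LCN2 samples. These markers moved with the 12 genes that fell. With the marker score as a covariate, the median log2 fold change of those 12 went from -1.79 to -1.27, with a median SE of 0.20 before and 0.23 after. Limma then called no gene, and 3299 had an unadjusted p under 0.05.

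Genes of cell division were higher in gonadal fat with the LCN2 vector. All 30 proliferation genes had a positive log2 fold change, with a median of 0.78, and in all 4 LCN2 samples the list's median lay above that of every GFP sample. Camera called the list (adjusted p = 8.60e-12, but adjusted p = 0.973 and unadjusted p = 0.0766 with an estimated correlation). None of the 30 passed over all genes and 14 did with p adjusted over the list alone. Cdk1, the mitotic kinase gene, had a log2 fold change of 1.31 ± 0.24 and Cenpe, a kinetochore motor gene, one of 1.21 ± 0.22. Extracellular matrix genes had a median of 0.54, with 33 of 45 above 0, 11 passing over the list alone and none over all genes. Here the medians per sample overlapped, with GFP replicate 4 at 0.35 and LCN2 replicates 1, 3 and 4 at 0.20, 0.24 and 0.18. The fibrillar collagen genes Col5a1, with 0.82 ± 0.16, and Col5a2, with 0.96 ± 0.23, led this list. Camera called it (adjusted p = 1.54e-05, but adjusted p = 0.973 and unadjusted p = 0.205 with an estimated correlation).

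Camera called 5 more lists in gonadal fat, each with an adjusted p of 0.973 with an estimated correlation and no member past the test over all genes. Cholesterol synthesis genes were higher in 22 of 24 members (median 0.35, adjusted p = 0.000926, 1 member over the list alone), with Hmgcs1, the synthase before HMG-CoA reductase, at 1.71 ± 0.30. Thermogenic genes were higher in 16 of 19 (median 1.04, adjusted p = 0.00460, 1 over the list alone), with Prdm16, a regulator of brown and beige fat, at 0.90 ± 0.21 and Cpt1b at 1.58 ± 0.47. Cpt1b was close to the filter, with a normalized count of 35.3 ± 21.0 (SD, n = 4) against 10.8 ± 5.95 (SD, n = 4), and its groups overlapped. It shares 81.4% of its exonic bases with the read-through gene Gm44502. Endothelial markers were higher in 17 of 18 (median 0.27, adjusted p = 0.00305, none over the list alone), with Cdh5 at 0.58 ± 0.22 and Tie1 at 0.52 ± 0.20. Skeletal muscle markers were higher in 17 of 17 (median 1.75, adjusted p = 0.00980, none over the list alone), with Acta1 at 1.80 ± 0.59 and Mb at 2.32 ± 1.05. They took 0.218% of recovered reads in LCN2 replicate 4 and at most 0.0217% in the other samples. Circadian clock genes were lower in 14 of 19 (median -0.31, adjusted p = 0.0232, 2 higher and 5 lower over the list alone), while Arntl, an activator of the clock, was higher at 1.90 ± 0.49.

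With libraries left out, lists were tested at the preset correlation, and with all samples every gonadal list had an adjusted p of 0.973 with an estimated one. That shared value comes from the adjustment over lists. Before it, the smallest p by camera was 0.0743, for the mesothelial list. At the preset correlation the matrix, proliferation and mesothelial calls held without any 1 library. The muscle call ended without LCN2 replicate 4, GFP replicate 1 or GFP replicate 3 (adjusted p up to 0.796) and the endothelial call without GFP replicate 2 (adjusted p = 0.164). The thermogenic call ended without GFP replicate 4 or LCN2 replicate 1 (up to 0.150), the cholesterol call without GFP replicate 4 or LCN2 replicate 3 (up to 0.1001) and the circadian call without GFP replicate 3 or LCN2 replicate 1 (up to 0.168). Without GFP replicate 4, 13 lists were called instead of 8. The 7 gained were electron transport (adjusted p = 3.38e-07), the tricarboxylic acid cycle (0.00386), lipogenesis (0.01505) and adipocyte identity (0.0158), all lower, and inflammatory cytokines (0.0131), antigen presentation (0.0154) and immediate early genes (0.0158), all higher. Lipogenesis was also called lower without LCN2 replicate 3 (0.0371). Fatty acid oxidation was called higher without GFP replicate 2 (0.000956), GFP replicate 3 (0.00719) or LCN2 replicate 2 (0.0183). Antigen presentation was called higher without LCN2 replicates 2, 3 or 4 (0.0183, 0.00976 and 0.0330). Without LCN2 replicate 4 inflammatory cytokines (0.0440), the interferon response (0.00156) and T and NK cell markers (0.0122) were called higher. Without both LCN2 replicate 4 and GFP replicate 2, muscle markers were still called higher (0.0166), the endothelial call ended (0.211) and fatty acid oxidation was called higher (0.000759). Without the 3 libraries highest in hepatocyte genes all 8 calls held, and macrophage markers (0.00476) and the interferon response (0.0310) were called lower. Both removals were chosen after the values were seen.

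With all samples the other 26 gonadal lists were not called, with an adjusted p by camera between 0.0722 and 0.911. In the iron handling list 1 of 30 members rose, Tfr2, and the list itself was not called (adjusted p = 0.534). No member passed in the lists of the electron transport chain, the mitochondrial genome, mitochondrial biogenesis, the tricarboxylic acid cycle, fatty acid oxidation, adipocyte identity, lipolysis, lipogenesis and insulin signalling. The same held for inflammatory cytokines, the interferon response, antigen presentation, oxidative stress, sex steroids, the unfolded protein response and immediate early genes. It also held for markers of macrophages, T and NK cells, B cells, fibroblasts, mammary epithelium, reproductive tract, erythroid cells, smooth muscle and nerve. With p adjusted over the list alone, 3 inflammatory genes passed, and 1 gene each in the lists of iron handling, adipocyte identity, lipolysis, sex steroids and mammary epithelium. The median, the mean and the test had the same sign in every called list, and differed in sign in 7 of the 26 others.

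In subcutaneous fat, limma called 0 of 20302 genes, with a smallest adjusted p of 0.308. An unadjusted p under 0.05 was found for 2851 genes, where chance gives 1015 on average. That count was 919 without GFP replicates 1 and 2, which held lymph node transcripts, and 1790 with the lymph node marker score as a covariate. With 1 sample left out it was 1859 without GFP replicate 1, 1445 without GFP replicate 2, 1832 without LCN2 replicate 2 and 1776 without LCN2 replicate 3, but 3895 without GFP replicate 3 and 3822 without GFP replicate 4. With sample quality weights it was 5831. No other test or setting run on these values called a gene, and no count test was possible on rlog values. All values of named genes here are given without a call. Among the 10 with the smallest p on the higher side with the LCN2 vector were Endou, Atp6v0d2, Slc7a8, Cdkl4, Serping1, Naaa, Setd7 and Ednrb. Slc7a8, an amino acid transporter gene, had an rlog of 9.97 ± 0.25 (SD, n = 4) against 9.09 ± 0.17 (SD, n = 4). Atp6v0d2, a proton pump subunit gene, had a difference of 0.62 ± 0.09 (SE) and Serping1, the complement inhibitor gene, one of 0.48 ± 0.08. On the lower side were Rexo5, St3gal6, Nat8l, Sfxn1, Rpl10a-ps2, Cept1, Epop, Hs3st3b1, Fam117a and Acacb. Acacb, an acetyl-CoA carboxylase that restrains fatty acid oxidation, had an rlog of 11.73 ± 0.19 (SD, n = 4) against 12.80 ± 0.50 (SD, n = 4). Nat8l, which makes N-acetylaspartate, had a difference of -0.45 ± 0.08. Rpl10a-ps2 is a pseudogene that may share reads with its parent gene. St3gal6 and Cept1 share 26.0% and 24.7% of their exonic bases with genes on the opposite strand.

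The lists of nuclear-encoded electron transport, the tricarboxylic acid cycle, fatty acid oxidation, thermogenic genes and lipogenesis were called lower in subcutaneous fat with the LCN2 vector. Those of the mitochondrial genome and of mitochondrial biogenesis were not called (camera, adjusted p = 0.0646 and 0.0950). Of 78 nuclear-encoded electron transport genes 73 had a negative difference, with a median of -0.10 (camera, adjusted p = 8.52e-07, but adjusted p = 0.828 with an estimated correlation). Ndufa6 had -0.23 ± 0.06 and Atp5g2 -0.19 ± 0.05. Tricarboxylic acid cycle genes were lower in 17 of 18 (median -0.11, adjusted p = 0.0152), with Idh3b at -0.22 ± 0.09 and Suclg2 at -0.13 ± 0.06. Fatty acid oxidation genes were lower in 17 of 24 (median -0.11, adjusted p = 0.0152), with the nuclear receptor gene Ppara at -0.58 ± 0.13 and Ehhadh at -0.33 ± 0.09. Thermogenic genes were lower in 17 of 19 (median -0.36, adjusted p = 0.00158), with Cox8b at -0.73 ± 0.25 and Cidea at -1.37 ± 0.48, and lipogenesis genes in 14 of 20 (median -0.22, adjusted p = 0.0248), with Acacb at -1.07 ± 0.23 and Fads1 at -0.16 ± 0.07. Each of these lists had an adjusted p of 0.828 with an estimated correlation. No member passed over all genes, and over the list alone 1 gene passed in fatty acid oxidation and 1 in lipogenesis. Thermogenic genes were called in opposite directions in the depots, though the list's medians per sample overlapped between groups in both. In gonadal fat 2 LCN2 samples lay above all GFP samples, and in subcutaneous fat 2 lay below all of them. The difference between depots was not tested.

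The lists of extracellular matrix, endothelium, fibroblasts, pericytes, the unfolded protein response and iron handling were called higher in subcutaneous fat with the LCN2 vector. Extracellular matrix genes were higher in 42 of 45 (median 0.48, adjusted p = 1.20e-08), with Mmp12, a macrophage metalloproteinase gene, at 1.29 ± 0.30 and Bgn, the proteoglycan biglycan, at 0.65 ± 0.19. Endothelial markers were higher in 17 of 18 (median 0.33, adjusted p = 2.85e-05), with Tie1 at 0.50 ± 0.16 and Cdh5 at 0.52 ± 0.18. Progenitor and fibroblast markers were higher in 15 of 19 (median 0.25, adjusted p = 0.0124), with Sema3c at 0.64 ± 0.20 and Fbn1 at 0.89 ± 0.30, and pericyte and smooth muscle markers in 10 of 12 (median 0.25, adjusted p = 0.0493), with Rgs5 at 0.62 ± 0.14 and Mustn1 at 0.39 ± 0.13. Unfolded protein response genes were higher in 22 of 26 (median 0.09, adjusted p = 0.00837), with Sel1l at 0.23 ± 0.07 and Edem1 at 0.34 ± 0.11. Iron handling genes were higher in 21 of 29 (median 0.09, adjusted p = 0.0493), with Heph, an iron oxidase gene, at 0.54 ± 0.10 and Tfr2 at 0.42 ± 0.16. Each had an adjusted p of 0.828 with an estimated correlation and no member past the test over all genes. Over the list alone, 1 gene passed in iron handling and 1 among pericyte markers.

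Lymphocyte markers separated 2 subcutaneous libraries from the rest. Markers of B cells and lymph node lay 3.10 and 2.04 above the mean in the median in GFP replicates 1 and 2, 1.41 above in LCN2 replicate 4, and at least 1.05 below in the other samples. Markers of T and NK cells lay 2.18 and 1.80 above in GFP replicates 1 and 2 and below the mean in the other samples. Camera called both lists lower with the LCN2 vector (adjusted p = 0.00561 and 3.83e-05, but adjusted p = 0.828 with an estimated correlation). Jchain had a difference of -0.95 ± 0.35, Cd3g one of -1.80 ± 0.78 and Klrb1c one of -0.25 ± 0.09. Ccl21a, a chemokine gene of lymph node stroma, had an rlog of 7.73 ± 0.91 (SD, n = 4) against 9.72 ± 1.70 (SD, n = 4). Skeletal muscle markers were called lower too (11 of 14, median -0.23, adjusted p = 0.0493, adjusted p = 0.828 with an estimated correlation), with Myh1 at -0.37 ± 0.12 and Myh4 at -1.07 ± 0.50. No member of these 3 lists passed, over all genes or over the list alone. Without GFP replicates 1 and 2, a choice made after seeing the data, 12 lists were called. The electron transport and matrix lists were among them, with an adjusted p of 0.00431 each, or 0.851 each with an estimated correlation, which gave 0.828 with all samples. With the B cell and lymph node score as a covariate, also chosen after seeing the data, they had 0.000145 and 1e-06 at the preset correlation, and the B cell and lymph node list was no longer called (0.184). Without the 2 libraries their median differences were -0.04 and 0.26, against -0.10 and 0.48 with all samples. With all samples the matrix list was lowest in GFP replicates 1 and 2, at -0.57 and -0.46, while electron transport stood at 0.15 and 0.06 there and at 0.13 and -0.14 in GFP replicates 3 and 4. Gained were cholesterol synthesis (adjusted p = 0.0204), immediate early genes (0.0397) and macrophage markers (0.000380), higher, and the circadian clock (0.00611) and mammary epithelium (0.000380), lower. The lymphocyte, muscle, pericyte, fibroblast, lipogenesis and tricarboxylic acid cycle lists were not, with an adjusted p between 0.0758 and 0.976.

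**Figure D3:**
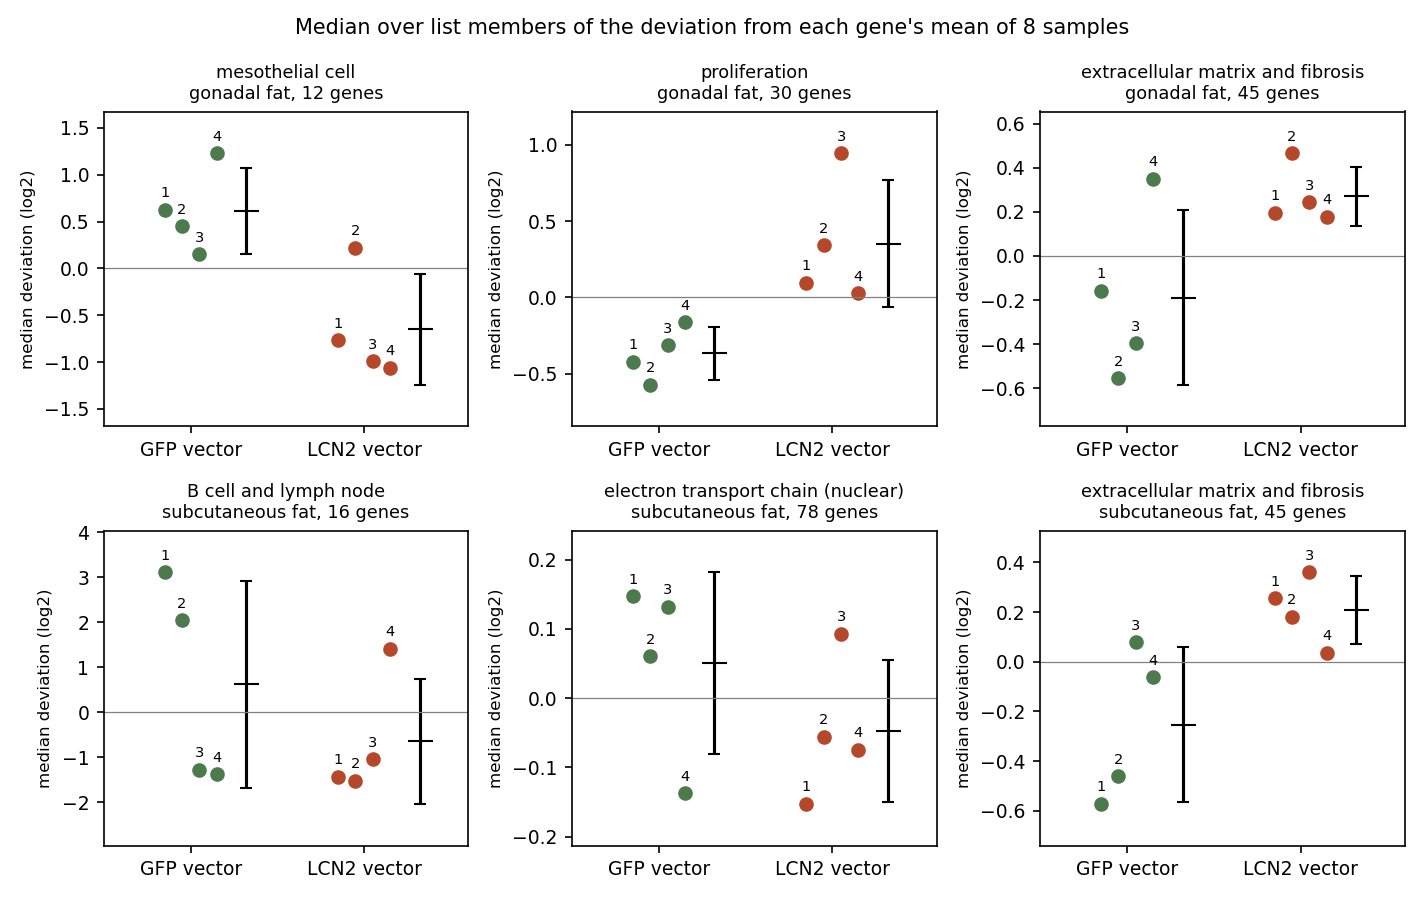
For 6 gene lists, the median over members of each sample's deviation from the gene's mean over 8 samples, on a log2 scale, with replicate numbers above the points and the mean ± SD of 4 samples beside them. GFP replicates 1 and 2 stand at 3.10 and 2.04 for B cell and lymph node markers in subcutaneous fat, and mesothelial markers in gonadal fat are highest in GFP replicate 4 at 1.23.

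At the preset correlation the electron transport, thermogenic, matrix, T and NK cell and endothelial calls in subcutaneous fat held without any 1 library. With all samples no list was called with an estimated correlation (adjusted p = 0.828 or more). Before adjustment over lists, camera then gave 0.0843 for the matrix list and 0.372 for electron transport. The unfolded protein response call ended without LCN2 replicate 1 (adjusted p = 0.0756), and the fibroblast and B cell calls without GFP replicate 1 or LCN2 replicate 1 (up to 0.172 and 0.1004). The tricarboxylic acid cycle call ended without GFP replicates 1 or 3 or LCN2 replicate 1 (up to 0.182) and the fatty acid oxidation call without GFP replicate 3 or LCN2 replicates 1 or 4 (up to 0.0863). The lipogenesis and muscle calls ended without GFP replicates 1 or 3 or LCN2 replicates 1 or 4 (up to 0.217 and 0.352). The iron handling call held only without GFP replicate 2 or LCN2 replicate 2, and was lost without any of GFP replicates 1, 3 and 4 or LCN2 replicates 1, 3 and 4 (up to 0.182). The pericyte call held only without GFP replicate 4 or LCN2 replicate 3, and was lost without any of GFP replicates 1, 2 and 3 or LCN2 replicates 1, 2 and 4 (up to 0.297). The number of lists called was 8 without GFP replicate 3 and 6 without LCN2 replicate 1, against 14.

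With all samples the other 21 subcutaneous lists were not called, with an adjusted p by camera between 0.0548 and 0.905. They were the mitochondrial genome, mitochondrial biogenesis, adipocyte identity, lipolysis, cholesterol synthesis, insulin signalling, inflammatory cytokines, the interferon response, antigen presentation, oxidative stress and sex steroids. The others were proliferation, immediate early genes, the circadian clock, and markers of macrophages, neutrophils, mesothelium, mammary epithelium, reproductive tract, erythroid cells and nerve. With p adjusted over the list alone, 1 gene each passed in the lists of adipocyte identity, macrophages and reproductive tract, and none over all genes. The median, the mean and the test differed in sign in 3 of these 21 lists and in none of the 14 called. With 1 sample left out, the interferon response was called higher without GFP replicates 1 or 4 or LCN2 replicates 2, 3 or 4 (adjusted p from 0.00172 to 0.0332). Macrophage markers were called higher without GFP replicate 2 or LCN2 replicate 2 (0.00282 and 0.000395) and erythroid markers without GFP replicate 4 or LCN2 replicate 2 (0.00570 and 0.0270). Cholesterol synthesis was called higher without GFP replicate 1 or LCN2 replicate 1 (0.02 and 0.0152). The mitochondrial genome was called lower without GFP replicate 4, LCN2 replicate 2 or LCN2 replicate 3 (0.0217, 0.00983 and 0.0468) and mitochondrial biogenesis without GFP replicate 2 (0.0355). Also called lower were proliferation without LCN2 replicate 2 (0.000379), and the circadian clock and mammary epithelium without GFP replicate 1 (0.0249 and 0.02).

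The depots could be compared only by setting their separate tests side by side. No gene passed in both, since none passed in subcutaneous fat. Of the 20 gonadal genes 16 were tested in subcutaneous fat, and 13 had a difference of the same sign there. With p adjusted over these 16, D430019H16Rik passed, with a difference of 1.01 ± 0.24 (limma, adjusted p = 0.0386). Car12 had 0.38 ± 0.12, Tfr2 0.42 ± 0.16 and Tmem255a 0.19 ± 0.12, the last with the opposite sign. Across 19109 genes the fold changes of the depots had a Pearson correlation of 0.27 and a Spearman correlation of 0.38. Without subcutaneous GFP replicates 1 and 2 these were 0.45 and 0.50, and genes are not independent replicates. At an unadjusted p under 0.05, 542 genes were higher and 609 lower in both depots, where independent lists give 118 and 87.5, and 10 went opposite ways, where they give 204. Without subcutaneous GFP replicates 1 and 2, 221 genes were higher and 113 lower in both, where independent lists give 39.7 and 23.8, and 5 went opposite ways, where they give 63.0. The labels leave open whether both depots came from the same mice, and shared mice would raise this overlap with no effect of the vector.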

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

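The tests on muscle transcripts, on lymph node tissue and leukocytes in subcutaneous fat, and on the lists without those libraries were chosen after the values they rest on had been seen. Of 214 groups of 4 values examined for a sample far from the others, 7 stood out, where unselected and independent groups would give about 11. Many of the 214 were genes chosen for a small p, and groups share samples, so 11 is no firm reference here. In each of the 7, the gap to the nearest sample took more of the group's range than the 95% critical value of Dixon's test for 4 samples. In gonadal fat this share of the range was 0.864 for Mtss1l and 0.873 for Itga7, both lowest in LCN2 replicate 1, and 0.880 for Lzts1, highest in GFP replicate 4. In subcutaneous fat it was 0.889 for Ehhadh, highest in GFP replicate 3, 0.925 for Myh4, highest in LCN2 replicate 3, and 0.866 for the progenitor and fibroblast list, lowest in GFP replicate 1. For the B cell and lymph node list it was 0.837, with LCN2 replicate 4 at 1.41 and the other LCN2 samples at -1.52 to -1.05.

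The 20 genes called in gonadal fat were more than any other split of the 8 samples into 4 and 4 gave. The highest other was 5, so 1 of 35 splits was as large, the smallest share this test can give. Several patterns were tested this way without correction, so that rank alone does not exclude chance. For the 12 genes that fell, the median log2 fold change was -1.72 without LCN2 replicate 4, against -1.79 with all samples. Their fall was thus not carried by that library alone. The test by calls was undecided, since without that sample 2 of the 12 passed, Tmem255a and Xpnpep2. The 12 were chosen for their fall with that sample included, which favours genes low in every LCN2 sample. Neither result can thus decide whether skeletal muscle in that library contributed. A smaller share of mesothelial cells may account for part of the fall: among samples of 1 group, the 12 genes had a median correlation of 0.80 with the score of the 12 markers, none of which is among them, against 0.45 at the 95th percentile of 1000 random sets matched on expression. With that score as a covariate their median was -1.27 (median SE 0.23) against -1.79 (median SE 0.20). The calls ended with a smaller fold and a larger SE. What part of the fall goes with the share of mesothelial cells cannot be read from this. Bnc1, itself a marker in the score, also stayed at -0.85 or lower in every alternative, this one included. Whether such a share would come from how the tissue was dissected or from LCN2 was not tested.

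In subcutaneous GFP replicates 1 and 2, lymphocyte markers were high. Leukocytes of all kinds are argued against, since 28 macrophage markers differed by -0.23 in the median there. Lymph node tissue in the piece may account for it: Ccl21a, Ccl19, Cxcl13 and Madcam1, which mark lymph node stroma and vessels, were higher by 2.55 in the median, in the lower of the 2 libraries over the mean of the others, and least so for Madcam1. Of these, Ccl21a and Ccl19 are in the B cell and lymph node list, whose 16 members were all measured in gonadal fat too. In LCN2 replicate 4, whose B cell and lymph node list also stood high, at 1.41, the same 4 genes were higher by only 0.07 in the median, so the source of its markers stays open.

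The lower electron transport list and higher matrix list with the LCN2 vector in subcutaneous fat stayed called at the preset correlation without GFP replicates 1 and 2 (adjusted p = 0.00431 each) and with the B cell and lymph node score as a covariate (0.000145 and 1e-06). Over samples, the electron transport mean differed by -0.11 ± 0.08 (SE), by -0.05 ± 0.11 without those libraries and by -0.08 ± 0.09 with the covariate, and the matrix mean by 0.47 ± 0.17, 0.22 ± 0.11 (95% interval -0.09 to 0.53) and 0.31 ± 0.08 (0.12 to 0.51). Lymph node tissue, an effect of LCN2 and chance cannot be told apart here, because the 95% interval of the electron transport difference included 0 each time, that of the matrix did without the 2 libraries, and the score, also high in LCN2 replicate 4, left T and NK cell markers called lower (0.000142). For chance, 18 of 35 splits of the samples called 14 lists or more, the highest 20, in gonadal fat 34 of 35 splits called 8 or more, the highest 23, and for genes in subcutaneous fat all 35 splits called at least 0 and 1 split called 16. Chance was thus not excluded for the number of lists called in either depot, and the preset correlation of 0.01 lay below those estimated for the called lists, 0.14 to 0.87 in gonadal and 0.11 to 0.84 in subcutaneous fat.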

How the results depend on the processing

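The limma fit with TMM scaling, other pseudocounts, covariates, removed sets of libraries and the overlaps of depots with rlog values in both or without libraries were chosen after seeing the data. The edgeR test had been planned for counts, and its run on recovered reads was added after seeing the data. The cause of each shift below was not tested, except that fits without libraries have fewer samples and the stricter filter fewer genes.

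The gonadal count of 20 genes became 6 with library totals, 10 with totals without the 10 most abundant genes, 11 with a mean of at least 50 reads, 776 with DESeq2, 12 with limma-voom, 65 with quality weights and 75 at an adjusted p under 0.10. It was 0 with the mesothelial score as covariate, 0 without the 2 libraries with the highest medians of muscle markers and 0 without the 3 with those of hepatocyte genes. Leaving out each sample gave 1 to 66. It stayed between 14 and 22 with the deposited size factors replaced by upper-quartile or TMM scaling, no filter, rlog values, edgeR, a fold change limit or other pseudocounts. DESeq2 size factors were not run as a separate scaling, because the deposited values already carry them. The 11 named genes kept their sign in each of these fits. They were chosen with groups that did not overlap, so leaving out libraries could not change it. Of the 11, DESeq2 called 11, edgeR 8, limma-voom 4 and limma with library totals 4. With the mesothelial score as covariate 0 of them passed.

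Replicate numbers did not pair the samples: deviations of same-numbered samples correlated at -0.36 to 0.42 in gonadal and -0.36 to 0.34 in subcutaneous fat, and 1 of 4 pairs in each depot correlated best with its own number. With the replicate block limma called 0 genes in gonadal and 0 in subcutaneous fat, with 2636 and 3200 at an unadjusted p under 0.05, and camera 8 and 12 lists.

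Lcn2 passed in gonadal fat only with DESeq2 (log2 fold change 2.08), its adjusted p lying between 1.28e-05 and 0.495 over 25 alternatives. Subcutaneous genes stayed at 0 and Lcn2 there did not pass in any of 18. Lists called were 0 in each depot with an estimated correlation and 0 with fry, and 6 to 13 in gonadal and 6 to 18 in subcutaneous fat with 1 sample left out. The overlap of depots was 0 at an adjusted p under 0.10, 1151 genes at an unadjusted p under 0.05, 1150 with rlog values in both depots and 334 without subcutaneous GFP replicates 1 and 2. Depth limits low genes in gonadal fat and is unknown in subcutaneous fat.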

Other observations

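The genes and the hepatocyte list in this and the next paragraph were chosen after their values were seen. Lep, the satiety hormone gene of fat cells, had a normalized count of 69700 ± 16459 (SD, n = 4) with the LCN2 vector and 28202 ± 6293 (SD, n = 4) with GFP in gonadal fat, a log2 fold change of 1.30 ± 0.23 (limma, adjusted p = 0.0964). In subcutaneous fat its rlog was 15.53 ± 0.34 against 14.43 ± 0.29 (SD, n = 4), a difference of 1.10 ± 0.20 (limma, adjusted p = 0.308). It did not pass in either depot, and in both all LCN2 samples lay above all GFP samples. Mest, Sfrp5 and Bmp3, genes linked to fat cell enlargement, had log2 fold changes of 2.66 ± 0.97, 1.65 ± 0.83 and 0.41 ± 0.32 in gonadal fat and differences of 1.78 ± 0.68, 1.29 ± 0.36 and 0.68 ± 0.24 in subcutaneous fat. None passed, and the groups overlapped for each in both depots, with Mest at 19715 in gonadal GFP replicate 4, above 3 of the LCN2 samples. Ucp1, the uncoupling protein of brown and beige fat, ran from 4.97 to 1081 in gonadal GFP samples and from 3.03 to 7819 in gonadal LCN2 samples, a log2 fold change of 1.90 ± 2.63 (limma, adjusted p = 0.793). In subcutaneous fat its rlog was 6.96 ± 1.29 against 9.69 ± 2.26 (SD, n = 4), a difference of -2.73 ± 1.11 (limma, adjusted p = 0.336) that did not pass. The signs were opposite, and the difference between depots was not tested.

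In gonadal fat the hepatocyte transcripts Alb and Apoa1 differed between samples of 1 group. Alb, the albumin gene, had normalized counts of 9989, 11019 and 28487 in GFP replicate 1 and LCN2 replicates 1 and 2, and between 1271 and 3198 in the other samples. Apoa1, an apolipoprotein gene, had 956, 1978 and 2748 in the same 3 and between 83.4 and 232 in the others. A list of 22 hepatocyte genes lay 1.72, 2.04 and 3.20 above the mean in the median in those libraries and below it in the rest. In subcutaneous fat the list lay 0.59 and 1.95 above the mean in GFP replicates 1 and 2, the libraries with high lymphocyte markers, and below it in the other 6. Alb had an rlog of 13.00 in GFP replicate 2 and between 10.73 and 11.41 in the others.

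The hypotheses below were formed on these data. DESeq2 called many more gonadal genes than limma, and single libraries could have driven the extra calls, but 85.2% of the 750 genes it alone called and limma tested had groups that did not overlap. This share does not show that the calls are true, since in 10 other splits with at least 50 such genes it ran from 14.5% to 95% and was as high in 4. Its 776 genes were more than any other split gave, the highest being 515, so 1 of 35 splits was as large. That is the smallest share this test can give, and alone it does not exclude chance. In simulated data with noise independent between genes 24.9% of its calls were false, and the share may differ in these data.

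Same-numbered samples of the depots may come from the same mouse. Their deviations from the group means had a mean correlation of 0.20 across 19108 genes without Lcn2, from -0.08 to 0.45, and a share of 0.00868 of all pairings within groups gave as high a mean. A shared order of sample handling was not tested. The correlation of fold changes between depots, 0.27, was reached in 3 of 35 splits of the subcutaneous samples (highest other 0.34) and in 18 of 35 splits applied to both depots by number (highest other 0.50), so chance was not excluded. Of genes with an unadjusted p under 0.05 in both depots and in 1 direction there were 1151 in the real split and at most 1033 in the others.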
